A study of Rattus norvegicus with 12 samples.

How the data were processed

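The series holds polyA RNA sequencing of periaqueductal grey tissue from 12 male Sprague Dawley rats, 6 sired by saline-treated and 6 by morphine-treated males. Per the labels' protocols, tissue was dissected and frozen, RNA was extracted with Trizol and a column kit, and libraries were made with an NEBNext Ultra kit. The submitters' processing notes name FastQC 0.11.9, Trimmomatic 0.39, HISAT2 2.2.0, SAMtools 1.11, StringTie 2.1.2, DESeq2 1.28.1 and the genome build Rnor_6.0. Per the file headers, the per-sample transcript files were written by StringTie 1.3.6 in its expression estimation mode against an annotation merged over the series, so the version differs between the notes and the headers. Whether the reads were paired or stranded is not given in the sources used here, so overlapping genes on opposite strands are reported without telling their reads apart.

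Each of the 12 files deposited gives coverage (mean read depth per base, not normalized), FPKM and TPM for 76232 transcripts, of which 41063 are annotated and 35169 were assembled in the series. The table of the whole series that the authors deposited holds log2 values, which matched log2(FPKM + 1) of the 41063 annotated transcripts in each library's own file to within 4.9e-08. It is therefore a table of transcripts, not of genes. The test fixed before the data were examined had assumed gene values in that table, with genes at a mean of at least 3 kept, and gave TPM summed over a gene's transcripts as the fallback for a table that could not be matched to the samples. The columns could be matched, but the table held no gene values, so that fallback was used for the gene test after the files had been seen. A deposited TPM value is relative to the library's total, so a large change in a few abundant transcripts moves all others.

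TPM was summed over the transcripts of each locus that carry one symbol, with assembled transcripts given to the symbol of their locus where it has only one. This made 41596 genes, of which 24540 with a mean of at least 0.5 TPM over the 12 libraries were tested (16407 with a symbol and 8133 without). In 770 loci several symbols share assembled transcripts, and their values are uncertain. Assembled transcripts held 27.6% to 29.6% of the TPM of a library and most of the level of 4728 of the 16407 tested genes with a symbol. StringTie divides reads between overlapping transcripts and between near-identical copies, so single transcripts, gene families such as hemoglobins and metallothioneins, and pseudogenes are uncertain.

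Depth was taken from the median ratio of a transcript's coverage to its FPKM, which gives the total of bases behind FPKM. It was 4.39 to 6.03 gigabases per library. Reads per gene for one alternative were estimated with a read length of 135 bases, inferred from the values: among lowly covered transcripts, 18.5% had a number of covered bases within 1 base of a multiple of 135, where chance gives 2.22%. The depth therefore limits low genes most, and the interval of each log2 difference gives the precision. Pearson's r of log2(TPM + 1) between libraries had a median of 0.962 within groups and 0.964 between groups, and no 2 libraries were identical.

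Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjusted p under 0.05) on log2(TPM + 1), which understates the change of low genes. The design held the sire's treatment alone. Transcripts were tested in the same way at a mean of at least 0.5 TPM. Gene lists were tested with camera (preset correlation 0.01, two-sided, adjusted over the 38 lists with at least 4 tested genes), with an estimated correlation, with fry, and with an exact permutation of the score. The 39 lists held 761 genes, of which 725 were found and 694 tested. Further calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

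Genes were named by a rule written before the data were examined: genes past the threshold, then genes with a symbol that is not a placeholder in order of p until 20 are named, up to 4 genes with the smallest p from each list described, 10 fixed opioid and signalling genes, 6 transcripts with the smallest p, and sex and cell type markers. AC128848.1, Mt2A, Mt3, Irf7, Isg15, Rpl34, CYTB, Ucn and Cartpt outside these parts, and genes called under an alternative, were named after their values were seen. Gapdh was added outside these parts for comparison. The groups, the tests, the gene lists and most alternatives were also fixed before the data were examined.

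The gene test was tested on simulated data with normally distributed values, independent genes and the moderated spread of the real data. Of 24540 genes, 200 were changed by a fold of TPM + 1, not of TPM. It recovered 47.5% of genes changed 1.5-fold on that scale, 69.0% changed 2-fold and 95.5% changed 4-fold, with 4, 5 and 12 false calls. For the same fold of TPM, the recovery of low genes would be smaller. With 2 lists shifted by 0.3 on the log2 scale among independent genes, camera recovered 2 and called 0 others.

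The alternatives tried were the deposited log2 table, a pseudocount of 0.1, no filter, a mean log2 value of at least 6, quantile normalization, centring of samples, limma-voom, array quality weights, a robust and an untrended variance prior, the range of the animal numbers in the labels (276 to 313 against 358 to 384, 3 per group in each) as a term, consecutive animal numbers as a random effect, and leaving out each library. Annotated transcripts alone, whole loci, marker scores as terms, pairs of library numbers as a block and leaving out libraries with unusual markers were added after seeing the data. No genome of the files' build was used here, so sequences of shared genes were not compared. Gene neighbours were taken from RefSeq's annotation of GRCr8, without its coordinates. The result of 1 gene is not reported here.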

Results

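RNA sequencing of the periaqueductal grey, the midbrain region from which descending pain control and part of the analgesic action of opioids arise, was compared between male Sprague Dawley rats whose sires had received saline and male rats whose sires had received morphine. Each group held 6 libraries (saline-sired 1 to 6 and morphine-sired 1 to 6), each with its own animal number in the labels. The labels name no litter or sire, so the p-values treat the 12 animals as independent. The depth of a library, taken from the median ratio of transcript coverage to FPKM, ran from 4.39 to 6.03 gigabases with a median of 5.15. Of the Y-linked genes, Kdm5d (11.3 to 14.8 TPM, the deposited unit of transcript abundance) and Eif2s3y (38.3 to 61.8) were present in all 12 libraries, which goes with the male label. Ddx3y (mean 0.213) and Usp9y (mean 0.00443) lay below the filter, and Uty and Xist were not found under these symbols. Values below are TPM as mean ± SD with n = 6 per group, and changes are differences of log2(TPM + 1), morphine-sired minus saline-sired, ± standard error.

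The first comparison asked which genes differ in the offspring according to the sire's treatment. The mu opioid receptor gene Oprm1, whose product is the main target of morphine, stood at 12.6 ± 5.26 in saline-sired and 12.4 ± 4.07 in morphine-sired rats (SD, n = 6 each), a log2 difference of -0.01 ± 0.27. The delta receptor gene Oprd1 (log2 difference -0.02 ± 0.16), the kappa receptor gene Oprk1 (0.09 ± 0.18) and the nociceptin receptor gene Oprl1 (0.08 ± 0.08) did not pass the test either, nor did the enkephalin precursor Penk (-0.10 ± 0.26) and the nociceptin precursor Pnoc (0.10 ± 0.18). Pdyn, which encodes the dynorphin precursor, had a log2 difference of -0.47 ± 0.20, and Pomc, which encodes the precursor of beta-endorphin, was at 4.17 ± 1.02 and 5.54 ± 1.15 (0.35 ± 0.15). Both stayed below the threshold, with limma's unadjusted p of 0.0363 and 0.0437 and an adjusted p over the opioid list alone of 0.233 for each.

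**Figure D1:**
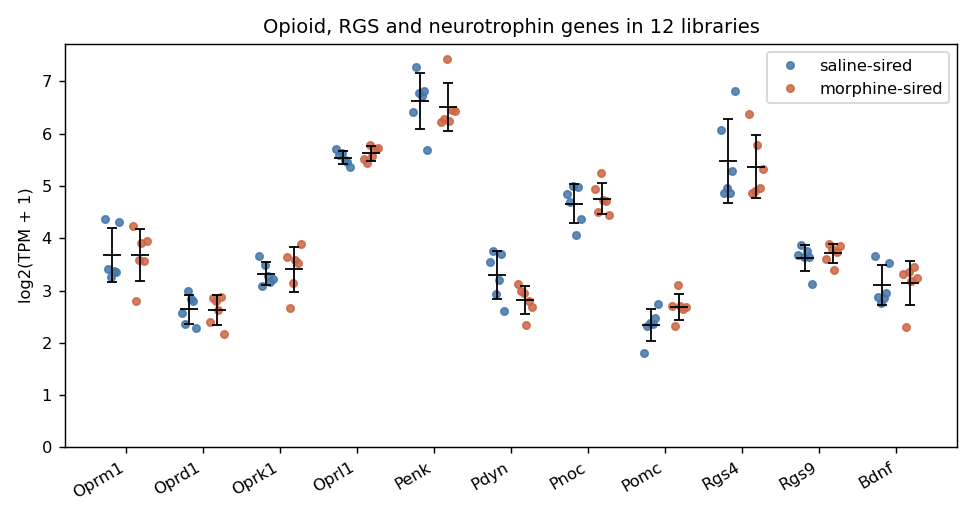
Each point is the log2(TPM + 1) value of one library for the opioid receptor and peptide genes, 2 genes of regulators of G protein signalling and Bdnf, in 6 saline-sired and 6 morphine-sired rats, with black bars for mean ± SD. The groups overlap for each gene shown, and Oprm1 spans 5.94 to 19.8 TPM over the 12 libraries.

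None of the 24540 genes tested passed an adjusted p of 0.05 with limma on log2(TPM + 1): 0 genes were higher and 0 lower. At an unadjusted p under 0.05 there were 790 genes (369 higher and 421 lower in morphine-sired), or 3.22% of those tested, where 1227 would be expected with no difference. limma-voom on reads estimated from coverage also gave 0 genes, with 3.19% at an unadjusted p under 0.05. The smallest adjusted p, 0.357, belonged to an unnamed single-exon locus on chromosome 1 (273402617 to 273402850, Rnor_6.0), at 0.945 ± 0.495 and 3.41 ± 0.839 (log2 difference 1.19 ± 0.19), and the next was 0.9998. Over all genes tested, the 95% interval of the log2 difference had a median half-width of 0.30. Among the 10847 genes with a mean of at least 10 TPM, it lay between -1 and 1 on the scale of log2(TPM + 1) for 95.6%. The groups did not overlap for 22 genes, where chance gives 0.216% of genes, or 53.1. One gene passed without saline-sired 4 (an unnamed locus on chromosome 1, 164916918 to 164921827, adjusted p 0.0398) and 1 without saline-sired 6 (the first locus above, adjusted p 0.0417), while the smallest adjusted p ranged from 0.0398 to 1 over the 12 fits that each left out a library.

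The 20 named genes with the smallest p are therefore given as values that did not pass. Mt1, annotated as a metallothionein gene, had the smallest p among genes with a symbol: 5.50 ± 0.644 in saline-sired and 10.6 ± 2.89 in morphine-sired rats (log2 difference 0.80 ± 0.15, limma adjusted p 0.9998), and its 6 morphine-sired values (7.11 to 14.8) all lay above its 6 saline-sired values (4.66 to 6.25). The files place it on chromosome 17 (78793336 to 78793724, plus strand, Rnor_6.0) as a model of 1 exon. They place Mt2A and Mt3 on chromosome 19 with 3 exons each, and RefSeq's annotation of GRCr8 places Mt1 next to Mt2A. This argues that the model is a copy of Mt1 rather than the gene itself, although sequences were not compared. Bend6 was at 133 ± 21.6 and 217 ± 51.5 (0.68 ± 0.15), and Isyna1, which encodes the enzyme of the first step of inositol synthesis, at 66.4 ± 2.64 and 75.2 ± 2.02 (0.18 ± 0.04). The other genes of this set with a higher mean in morphine-sired rats were Qsox1 (0.34 ± 0.08), Eva1b (0.31 ± 0.08), Pfdn6 (0.20 ± 0.05), Ydjc (0.28 ± 0.08), Tmub1 (0.20 ± 0.06) and Kcnma1. Kcnma1, a calcium-activated potassium channel gene, was listed at 0 to 0.274 in saline-sired and 0.0376 to 5.03 in morphine-sired libraries, in a locus shared by 2 symbols. Genes with a lower mean were Crot, which encodes a carnitine acyltransferase of peroxisomes (-0.38 ± 0.08), Zadh2 (-0.44 ± 0.10), Celf1, which encodes an RNA-binding splicing regulator (-0.41 ± 0.10), and the glutathione transferase gene Gsta3 (-0.68 ± 0.16). Further down were Appl1 (-0.65 ± 0.18), Inpp5k (-0.39 ± 0.11), Nelfcd (-0.22 ± 0.06), Rala (-0.27 ± 0.08), Fam126b (-0.90 ± 0.26), and Pcdh9 (-0.63 ± 0.15) and Mir1224 (-0.78 ± 0.19), the last pair in loci that 2 symbols share.

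The second comparison asked whether groups of genes fixed beforehand moved together. Of 38 gene lists, 6 passed camera's test with a preset correlation of 0.01: the choroid plexus, microglia, ribosomal protein and blood lists were shifted upward and the mitochondrial genome and oligodendrocyte lists downward in morphine-sired rats. With a correlation estimated from the data, 0 of the 38 lists passed, and the adjusted p of these 6 was 0.827 to 0.847 with an estimated correlation. An exact permutation test of the list scores over all assignments of the libraries gave no adjusted p under 0.963, and fry gave none under 0.942 for shifts in one direction and none under 0.953 for mixed ones.

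Among the 14 tested microglial markers, 12 had a higher mean in morphine-sired rats (mean log2 difference 0.10, camera adjusted p 0.00157). The complement gene C1qa was at 65.8 ± 8.08 and 79.6 ± 9.21 (0.27 ± 0.09), C1qc at 30.8 ± 3.12 and 36.9 ± 4.59 (0.25 ± 0.09), C1qb at 42.9 ± 5.40 and 49.4 ± 5.78 (0.20 ± 0.09) and the CSF1 receptor gene Csf1r at 58.9 ± 5.72 and 65.9 ± 4.68 (0.16 ± 0.07). With an estimated correlation the list's p was 0.0619 (adjusted p 0.827), and adjusted over the list alone 0 of its genes passed (smallest adjusted p 0.133). Without morphine-sired 2 the mean log2 difference was 0.09 and the camera adjusted p 0.0520, in a range of 2.59e-05 to 0.0520 over the 12 libraries left out in turn. The call was also lost without both saline-sired 2 and morphine-sired 2 (0.07, adjusted p 0.176) and with serotonergic, cholinergic and ependymal scores as terms (0.09, adjusted p 0.0668).

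All 12 tested choroid plexus markers had a higher mean in morphine-sired rats (mean log2 difference 0.49, camera adjusted p 0.000279), among them the folate receptor gene Folr1 (8.22 ± 3.20 and 14.8 ± 7.33), the prolactin receptor gene Prlr (1.80 ± 0.838 and 2.98 ± 0.678) and Clic6 (5.39 ± 3.03 and 9.27 ± 3.69). With an estimated correlation the p was 0.106 (adjusted p 0.847), and adjusted over the list alone 0 genes passed. Ttr, the most abundant choroid plexus transcript, ranged from 0.286 in saline-sired 6 to 413 in saline-sired 2 and 1756 in morphine-sired 2. The call was lost without morphine-sired 2 alone (mean log2 difference 0.18, camera adjusted p 0.224, in a range of 1.27e-06 to 0.224 over the libraries left out in turn) and kept without both saline-sired 2 and morphine-sired 2 (0.41, adjusted p 0.00271). All 6 tested blood genes, 5 of them hemoglobin genes, also had a higher mean (mean log2 difference 0.35, camera adjusted p 0.00639, and p 0.165, adjusted p 0.847, with an estimated correlation). Hba-a1 was at 391 ± 82.6 and 533 ± 303, and Hbb at 145 ± 26.3 and 205 ± 107. This call too was lost without morphine-sired 2 (mean log2 difference 0.12, camera adjusted p 0.275) and without saline-sired 3 (0.30, adjusted p 0.0502), in a range of 0.000793 to 0.275, and kept without both saline-sired 2 and morphine-sired 2 (0.21, adjusted p 0.0414). Adjusted over the list alone, 0 blood genes passed.

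Of 65 tested ribosomal protein genes, 51 had a higher mean in morphine-sired rats (mean log2 difference 0.06, median 0.04, camera adjusted p 0.00359), for example Rpl12 at 267 ± 48.1 and 306 ± 21.1 (0.22 ± 0.11). The annotated transcript of Rpl34, also in the list, was at 324 to 365 in saline-sired 3 and morphine-sired 2, 3 and 6. It was at 7.90 to 16.7 in the others, and how far this moves the list mean was not tested. With an estimated correlation the p was 0.319 (adjusted p 0.847), and adjusted over the list alone 0 genes passed. The call was lost without saline-sired 1 (mean log2 difference 0.03, camera adjusted p 0.207) and without saline-sired 6 (0.04, adjusted p 0.0840), in a range of 3.76e-05 to 0.207. These libraries also had the lowest serotonergic and cholinergic marker scores of their group, at -1.19 and -1.76 in saline-sired 1 and at -1.38 and -1.76 in saline-sired 6. With the serotonergic score as a term the mean was 0.08 (adjusted p 4.04e-05), with the cholinergic score added 0.06 (adjusted p 0.0364), and with the ependymal score added as well 0.06 (adjusted p 0.0668). Without saline-sired 1 and 6 and morphine-sired 1 it was 0.01 (adjusted p 0.917). All 13 genes of the mitochondrial genome had a lower mean (mean log2 difference -0.19, median -0.08, camera adjusted p 0.00696), such as ND6 (-0.14 ± 0.08) and ND1 (-0.10 ± 0.05). With an estimated correlation the p was 0.209 (adjusted p 0.847), and adjusted over the list alone 0 genes passed. In morphine-sired 6, CYTB was at 40.8 against 10351 to 11526 in the other libraries, while an assembled transcript listed at 0 elsewhere was at 4769 there. The mitochondrial call was lost without saline-sired 1 (mean log2 difference -0.15, adjusted p 0.0903), saline-sired 4 (-0.17, 0.0700) or morphine-sired 5 (-0.20, 0.0973), in a range of 9.18e-05 to 0.0973. Without morphine-sired 6 it was kept with a smaller mean of -0.08 (adjusted p 0.00832). Quantile normalization ended the mitochondrial call (-0.13, camera adjusted p 0.469) and the ribosomal one (0.04, camera adjusted p 0.337).

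Of 17 tested oligodendrocyte markers, 15 had a lower mean in morphine-sired rats (mean log2 difference -0.09, median -0.14, camera adjusted p 0.0147), such as Aspa, which encodes an enzyme that splits N-acetylaspartate (log2 difference -0.29 ± 0.14). Ermn went against the direction of the list (log2 difference 0.61 ± 0.30), without passing the test. With an estimated correlation the p was 0.346 (adjusted p 0.847), and adjusted over the list alone 0 genes passed. Leaving out any 1 of 7 libraries ended this call: saline-sired 3 (mean log2 difference -0.08, camera adjusted p 0.0524), saline-sired 4 (-0.08, 0.111), saline-sired 5 (-0.09, 0.0893), saline-sired 6 (-0.07, 0.0898), morphine-sired 1 (-0.04, 0.165), morphine-sired 3 (-0.03, 0.473) and morphine-sired 5 (-0.08, 0.0973), in a range of 8.49e-08 to 0.473. Among single omissions the mean was largest, at -0.19, without morphine-sired 2, and without both saline-sired 2 and morphine-sired 2 it was -0.24 (adjusted p 4.85e-10). Counting annotated transcripts alone turned the direction (mean log2 difference 0.07, adjusted p 0.431).

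**Figure D2:**
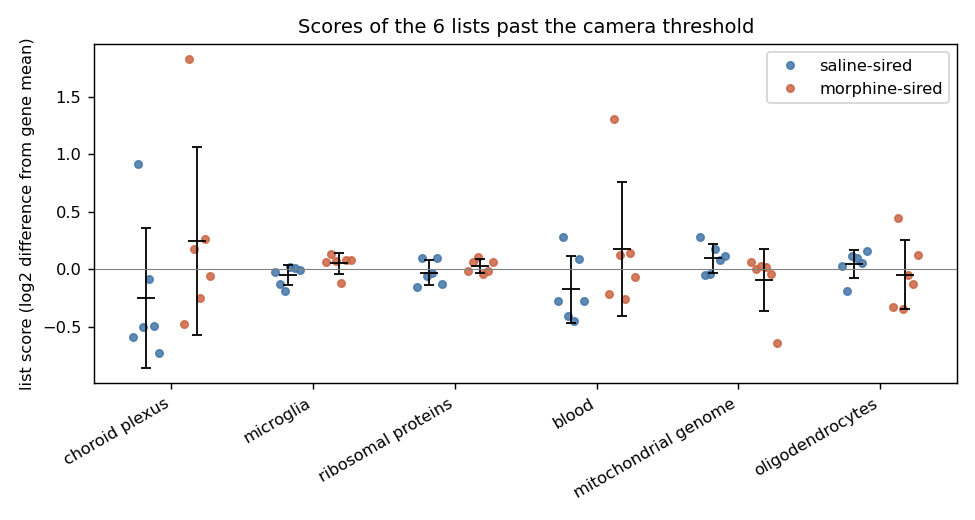
Each point is the score of one library, the mean over a list's genes of the log2(TPM + 1) value minus the gene's mean over 12 libraries, for the 6 lists that passed camera with a preset correlation. Black bars give mean ± SD of 6 libraries; morphine-sired 2 lies at 1.82 in the choroid plexus list and at 1.31 in the blood list, and morphine-sired 6 at -0.64 in the mitochondrial list.

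The signalling lists did not pass. The opioid receptor and peptide list (11 genes) had a camera adjusted p of 0.411 and the list of regulators of G protein signalling (17 genes) one of 0.415. In the latter, Rgs4 was at 50.4 ± 33.3 and 43.8 ± 21.3 (log2 difference -0.11 ± 0.37), Rgs9 at 11.4 ± 1.96 and 12.2 ± 1.61 (0.09 ± 0.12), Gnb5, the G protein beta subunit that partners Rgs9, at 55.4 ± 5.81 and 49.6 ± 2.70 (-0.15 ± 0.07), and Rgs5 at a log2 difference of -0.17 ± 0.08. The 35 tested opioid receptor effectors had a camera adjusted p of 0.592 (median log2 difference 0.01, mean -0.00), the GABA list 0.731 (median 0.01, mean -0.01), glutamate receptors 0.728, calcium channels 0.466, and sodium and potassium channels 0.904. In the last list the test pointed down with a median of -0.02 and a mean of 0.02, and Kcna2 was at 70.9 ± 30.8 and 40.2 ± 8.20 (-0.70 ± 0.26). The endocannabinoid list had an adjusted p of 0.731, neuropeptides 0.450 (Cartpt 0.79 ± 0.47, Ucn 0.92 ± 0.58) and neurotrophins 0.411 (Bdnf 0.04 ± 0.22). Adjusted over the list alone, 0 genes passed in each of these lists, as over all genes tested.

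Stress, clock and immune lists did not pass either. The glucocorticoid responsive list had a camera adjusted p of 0.731, and adjusted over the list alone 1 of its 17 genes passed, the model named Mt1 (0.00281), whose place in this list rests on its symbol. Immediate early genes had an adjusted p of 0.201 (Egr3 -0.46 ± 0.14) and the circadian clock list 0.731 (Cry2 -0.15 ± 0.06). The interferon response list was at 0.0503 (12 of 17 genes with a higher mean), and with an estimated correlation at p 0.338 (adjusted p 0.847). In it, Psmb9 was at 4.98 ± 0.651 and 6.88 ± 1.62 (0.38 ± 0.13). Cytokines and innate immunity were at 0.0570 (12 of 15 genes with a higher mean), and with an estimated correlation at p 0.0238 (adjusted p 0.827). There, C4b was at 1.39 ± 0.573 and 2.75 ± 1.05 (0.64 ± 0.21), in a locus shared by 2 symbols. Morphine-sired 5 and 6 had the highest scores in both lists (interferon 0.71 and 0.31, cytokines 0.21 and 0.17). The list of antigen presentation genes was at 0.334, epigenetic enzymes at 0.587, heat shock genes at 0.229, cholesterol synthesis at 0.411 and the nuclear-encoded respiratory chain at 0.731 (median -0.00, mean 0.00). Adjusted over the list alone, 0 genes passed in each of these lists other than the glucocorticoid one. Of the sex check genes, too few for a list test, Eif2s3y was at 52.3 ± 6.14 and 45.1 ± 3.35 (-0.21 ± 0.08), and passed when adjusted over its list alone (0.0470).

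Among the remaining cell type lists, astrocytes had a camera adjusted p of 0.0740 (12 of 13 genes with a higher mean, Gfap 0.27 ± 0.19), neurons 0.229 (Rbfox3 -0.26 ± 0.10, Nefh -0.75 ± 0.34), endothelial cells and pericytes 0.160, ependymal cells 0.411, and meninges and fibroblasts 0.904 (median 0.01, mean -0.01). Oligodendrocyte precursors were at 0.684, where the test and the mean (-0.03) pointed down and the median was 0.01. Of the regional neuron lists, serotonergic neurons were at 0.170, catecholamine neurons at 0.411, cholinergic neurons at 0.587, cerebellar neurons at 0.201, forebrain neurons at 0.170 and thalamic and collicular neurons at 0.411. Adjusted over the list alone, 0 genes passed in any of these lists.

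Markers of neighbouring nuclei differed far more between libraries than between groups. Tph2, the serotonin synthesis gene of the raphe nuclei, ranged from 0.450 in saline-sired 1 to 445 in saline-sired 2 (exact permutation p between groups 0.470), and Chat, the acetylcholine synthesis gene, from 0.0955 in saline-sired 1 to 36.4 in morphine-sired 3 (exact permutation p 0.729). Pcp2, a Purkinje cell gene, reached 166 in saline-sired 2 and at most 1.89 elsewhere. Tph2 and Chat were both low in saline-sired 1, saline-sired 6 and morphine-sired 1, with Tph2 at 0.450, 0.672 and 0.489 and Chat at 0.0955, 0.569 and 1.15. Gapdh, used in all cells, ranged from 2595 to 3067.

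**Figure D3:**
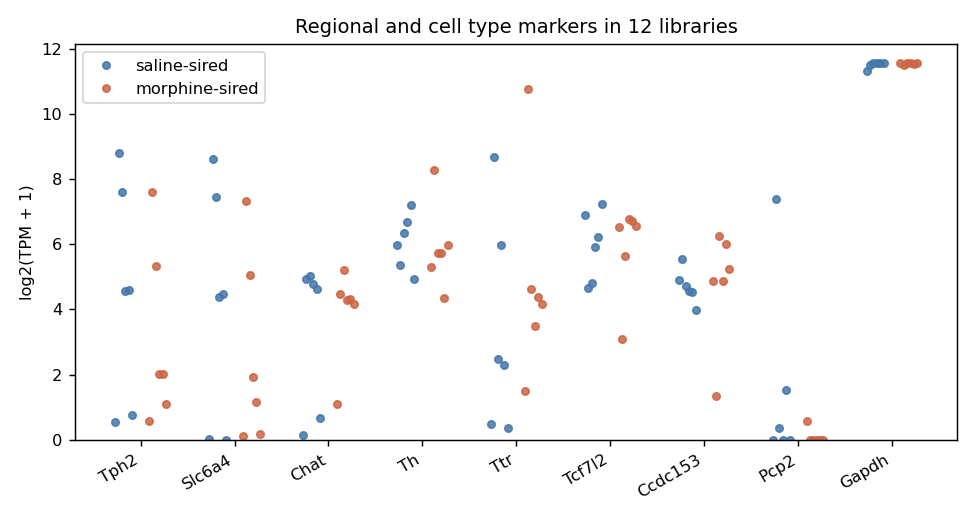
Each point is the log2(TPM + 1) value of one library for markers of serotonergic (Tph2, Slc6a4), cholinergic (Chat), catecholamine (Th), choroid plexus (Ttr), thalamic and collicular (Tcf7l2), ependymal (Ccdc153) and Purkinje (Pcp2) cells, with Gapdh for comparison. Tph2 spans 0.450 to 445 TPM, whereas Gapdh spans 2595 to 3067.

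The third comparison took single transcripts. Of 50419 transcripts tested, 1 passed, an assembled transcript of Gnao1, which encodes the alpha subunit of Go, a G protein through which opioid receptors signal. It lies on chromosome 19 (11515798 to 11564438, minus strand, Rnor_6.0), has 6 exons and is not in the annotation. It stood at 1.52 ± 0.645 in saline-sired and 10.6 ± 3.60 in morphine-sired rats (SD, n = 6 each; log2 difference 2.17 ± 0.23, limma adjusted p 0.0356), higher in 6 of 6 morphine-sired libraries than in any saline-sired one. The sum over the 7 transcripts of the locus was 166 ± 17.1 and 162 ± 25.8, a log2 difference of -0.04 with a 95% interval from -0.26 to 0.18. At an unadjusted p under 0.05 there were 1902 transcripts (3.77%).

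The Gnao1 transcript kept its call in 3 of the 12 fits that left out a library, and its adjusted p ranged from 0.00460 to 0.188 over them. The call was lost without saline-sired 1 (adjusted p 0.154), 2 (0.0974), 3 (0.0966), 4 (0.142) or 6 (0.0589) and without morphine-sired 1 (0.0696), 3 (0.0696), 4 (0.176) or 5 (0.188), with a log2 difference of 2.04 to 2.33 throughout. With all libraries, the call also ended on log2(FPKM + 1) and with pairs of library numbers as a block. The transcript's only exon in no other transcript (11564341 to 11564438) had a depth of 0.282 ± 0.487 in saline-sired and 2.71 ± 2.54 in morphine-sired libraries, against 15.4 ± 6.05 and 128 ± 58.5 assigned to its next exon. The 5 other transcripts with the smallest p did not pass: a single-exon transcript at the first locus above (adjusted p 0.570), assembled transcripts of AABR07073038.2 (log2 difference -3.17 ± 0.50, adjusted p 0.570) and of Arhgef1 (2.28 ± 0.36, adjusted p 0.570), and ones of Zfp385a (3.32 ± 0.56) and Ankhd1 (-1.12 ± 0.20), both with an adjusted p of 0.711. The summed levels of the Arhgef1, Zfp385a and Ankhd1 loci differed by -0.12, -0.17 and -0.07 on the log2 scale. The sum of the AABR07073038.2 locus was higher in morphine-sired rats, unlike its transcript, at 29.6 ± 7.94 and 37.8 ± 5.99. Its log2 difference was 0.37, with an interval from 0.02 to 0.72 that was not adjusted for the number of transcripts tested.

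**Figure D4:**
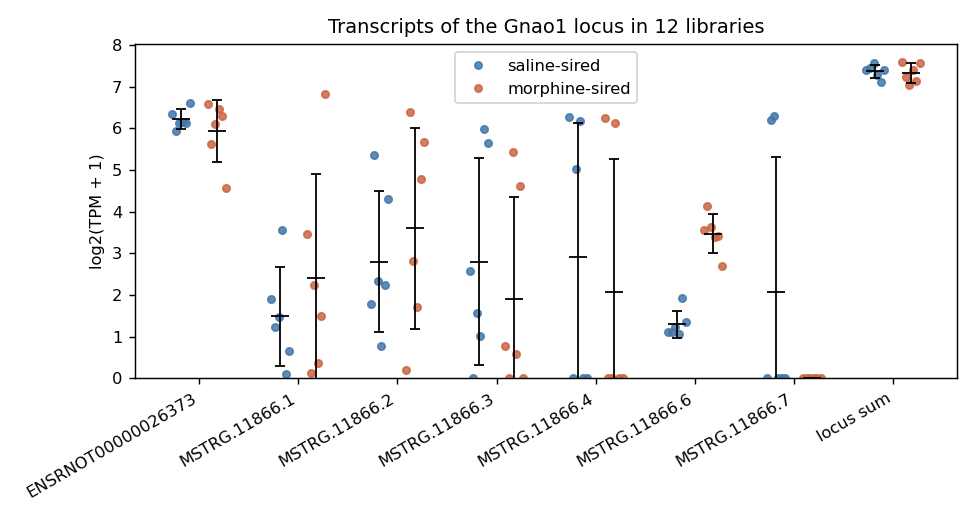
Each point is the log2(TPM + 1) value of one library for the annotated transcript and the 6 assembled transcripts of the Gnao1 locus and for their sum, with black bars for mean ± SD of 6 libraries. The transcript that passed the test separates the groups (1.52 ± 0.645 and 10.6 ± 3.60 TPM), the annotated transcript is at 74.7 ± 12.9 and 66.6 ± 26.8, and the sum overlaps.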

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

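All tests of explanations in this part were chosen after the results were seen. Within each group of 6, a library was singled out when its gap to the nearest other, as a share of the group's range, exceeded the critical value of Dixon's test, which chance does in about 1 of 20 groups. This was asked of list scores, library measures, the transcripts and the genes named in the text, a choice made after all named genes and then a smaller set had been looked at in the same way. Of 248 groups, 36 were singled out, where chance gives about 12.4. Some of these genes were named after their values were seen, and markers also enter the score of their list. The first count is therefore not a fair test against chance. Over list scores alone it was 10 of 76, where chance gives about 3.8.

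Morphine-sired 2 was singled out as highest in the scores of catecholamine neurons (gap 0.689), choroid plexus (0.681) and blood (0.746), and in Ttr (0.662) and Hba-a1 (0.779), and as lowest in Bdnf (0.770), Tcf7l2 (0.695) and Ccdc153 (0.716). Saline-sired 2 was highest in the cerebellar score (0.786), Pcp2 (0.793), Folr1 (0.653), Gfap (0.640) and the assembled Zfp385a transcript (0.934), and lowest in the oligodendrocyte score (0.635). Morphine-sired 1 was lowest in the cholinergic score (0.632) and Chat (0.746), and the only library of its group with Pcp2 above 0 (gap 1). Saline-sired 6 was lowest in Rgs9 (0.688), Cartpt (0.791) and Ucn (0.798), the urocortin gene of the Edinger-Westphal nucleus, and highest in the single-exon transcript of the unnamed chromosome 1 locus (0.662). Morphine-sired 3 was highest in neuropeptides (0.672), neurotrophins (0.647) and Penk (0.806), saline-sired 5 in Bend6 (0.629) and the Gnao1 transcript (0.670), and morphine-sired 5 in Mt2A (0.645).

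Morphine-sired 6 was lowest in the mitochondrial score (0.845) and highest in the AABR07073038.2 transcript (0.993), and morphine-sired 4 was lowest in the microglia score (0.721). Saline-sired 3 was highest in Rpl34 (0.944) and lowest in C1qc (0.777) and the AABR07073038.2 transcript (0.659). The last cases were low values of Gapdh in saline-sired 1 (0.754), of Eif2s3y in morphine-sired 5 (0.884) and of AC128848.1 in saline-sired 4 (0.779). Separately, 1 gene passed a test for an interaction of the sire's treatment with the range of animal numbers. It was AABR07044362.4 on chromosome 20 (3170034 to 3199279, limma adjusted p 0.00117 for the interaction). Its level was 0.00527 to 0.0144 in saline-sired 4, 5 and 6, the saline-sired libraries of the lower range, and 5.07 to 14.6 in the other 9 libraries. The call thus rests on near absence in these saline-sired animals, whose cause was not tested.

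The Gnao1 transcript that passed the test was weighed against a shift of reads between overlapping transcripts, a higher level of a transcript starting at its own exon, and chance. Its own exon was read at a median of 1.85% of the depth assigned to its next exon in the morphine-sired libraries, and at most 8.37%. If depth were even along a transcript, this would argue against such a transcript carrying the whole level of 10.6 TPM. The own exon is the first one and, at 98 bases, shorter than the inferred read length of 135. How far its place at the end lowers its depth was not tested. The own exon was deeper per gigabase in morphine-sired libraries (exact permutation p 0.00649), at 0.341 to 5.61 reads. That p was computed first and was set aside after its result was seen, in favour of the share of depth, because the transcript had been picked for its difference. A low level of such a transcript stays open. Of 100 splits of the 12 libraries, 74 gave at least 1 transcript, up to 9, so chance could not be excluded. Reads of shared exons assigned differently between libraries are a candidate explanation, since the locus sum differed by -0.04 on the log2 scale. Another assembled transcript of the locus was at 25.0 ± 38.8 TPM in saline-sired and at 0 in all morphine-sired libraries. The rest differed in both directions, such as 2.88 ± 3.99 and 21.3 ± 44.4 in a further one.

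Between libraries, Tph2 spanned 991-fold, Chat 381-fold and Tcf7l2 19.9-fold. Aligned bases differed by 1.38-fold between libraries, which argues against depth, and 4.70% of the sum of squares of the serotonergic score lay between the groups, which argues against the sire's treatment as the main source. The estimated correlation within 6 regional marker lists had a median of 0.440, against 0.231 for the other 32 lists. It was 0.730 for cholinergic, 0.698 for serotonergic, 0.567 for catecholamine and 0.312 for cerebellar neurons, but 0.136 for thalamic and collicular and -8.98e-05 for forebrain neurons. For the first 4 lists, tissue pieces cut at different positions are a candidate source, and the other 2 do not show it.

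Mt1 did not overlap between the groups. The number of genes without overlap, 22, was below the 53.1 that chance gives, so chance among the genes tested stays open. After removing group means, Mt1 followed AC128848.1, a gene beside Mt2A on chromosome 19 (r 0.772, permutation p 0.00417; Spearman's rho 0.762, permutation p 0.00540; r 0.727 without the 2 libraries farthest from the median; adjusted p 0.0125 over 3 genes compared). No relation passed the test for Mt2A (r 0.422, permutation p 0.171; rho 0.392, permutation p 0.208; r -0.0647 without the 2 libraries farthest from the median) or Mt3 (r -0.102, permutation p 0.746; rho 0.0979, permutation p 0.763; r 0.253 without 2 libraries). RefSeq's GRCr8 annotation places Mt1 next to Mt2A and lists other Mt1 copies as pseudogenes, so reads shared with another metallothionein gene may contribute. In the files, AC128848.1 (2 exons, 11302125 to 11302938) lies beside Mt2A on the same strand. It may therefore be the gene that GRCr8 names Mt1, although sequences were not compared. The 3 genes are thus not equal candidates as a source of shared reads. A common regulation would also relate Mt1 to AC128848.1. The relation with only 1 of the 3 genes does not decide between shared reads and common regulation. Mt2A itself differed by 0.26 ± 0.20 on the log2 scale. AC128848.1 differed by 0.22 to 0.54 over the alternatives, with no limma adjusted p under 0.602. These values leave a higher metallothionein level in morphine-sired rats undecided.

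The counts themselves were set against 100 of the 462 splits of the 12 libraries into 6 and 6, the real one included. For genes these splits decide nothing, since no split can give fewer than the real 0 (as many in 100, up to 3 in another split). For the share of low p and for the lists, chance could not be excluded. A share at an unadjusted p under 0.05 as high as the real 3.22% was found in 79, with up to 12.9%, and as many lists as the real 6 in 79, with up to 18. Splits with several times the real share point to a structure among the libraries other than the sire's treatment.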

How the results depend on the processing

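Marker scores and pairs of library numbers as terms, omission of several libraries, single annotated transcripts or whole loci, the list settings other than the estimated correlation, the number range and the left-out libraries, and the transcript settings other than pseudocount, filter and FPKM were chosen after the data were seen. The count of 0 genes held in 29 of 32 alternatives. It was 1 without saline-sired 4 or without saline-sired 6 (range 0 to 1 over the libraries left out in turn) and 1 on leaving out saline-sired 1 and 6 and morphine-sired 1 (AABR07044389.1, chromosome 20, 4510034 to 4517128, adjusted p 0.00159, in a range of 0.00159 to 1 over the smallest adjusted p of all alternatives), where the omitted saline-sired libraries had 7.68 and 10.5 TPM of it and the other saline-sired ones 0.540 to 1.36. The share of genes at an unadjusted p under 0.05 was 1.54% with a mean log2 value of at least 6, 5.23% with array quality weights, 6.09% with serotonergic, cholinergic and ependymal scores as terms, and 8.86% without saline-sired 2 and morphine-sired 2, and ran from 2.76% to 6.00% over the libraries left out in turn, highest without morphine-sired 2. The number of lists was 0 with an estimated correlation, 12 with array quality weights and 11 without saline-sired 2 and morphine-sired 2, and 4 to 9 over the libraries left out in turn. The oligodendrocyte list turned to a mean log2 difference of 0.0654 (adjusted p 0.431) with annotated transcripts alone, in a range of adjusted p from 4.85e-10 to 0.847 over 14 settings. The ribosomal call also ended with quantile normalization (mean log2 difference 0.04, adjusted p 0.337), annotated transcripts alone (0.08, 0.166) and array weights (0.03, 0.0565). The mitochondrial call ended with quantile normalization (-0.13, 0.469) and without saline-sired 1 and 6 and morphine-sired 1 (-0.17, 0.178), and the blood call with array weights (0.21, 0.106). The oligodendrocyte call ended with the serotonergic score (-0.08, 0.0755), with it and the cholinergic score (-0.08, 0.0667) and without those 3 libraries (-0.01, 0.401), and was kept with serotonergic, cholinergic and ependymal scores (-0.12, 7.34e-07) and with array weights (-0.14, 4.97e-05). With the serotonergic score, with the cholinergic one added and with the ependymal one added, the choroid plexus mean was 0.72 (4.28e-09), 0.86 (5.71e-12) and 0.83 (3.06e-10), and the blood mean 0.47 (4.04e-05), 0.59 (6.08e-07) and 0.55 (1.69e-05). The transcript count was 0 on log2(FPKM + 1), where the Gnao1 transcript had a log2 difference of 1.72 and an adjusted p of 0.0636 (0.0154 to 0.99998 over 6 settings), and 0 to 2 over the libraries left out in turn. Beyond fewer samples or genes in a fit, the cause was not tested. Of 602 values of the 20 genes with the smallest p, 5 had the other sign, in Isyna1, Celf1, Kcnma1, Eva1b and Nelfcd. Of 5870 values of 194 genes (Mt2A, Mt3 and AC128848.1 among them named after their values were seen), 154 in 54 genes had the other sign and 0 passed the threshold. Centring moved the median gene by at most 0.06 in a sample. The labels give no replicate number, only library numbers that alternate between the groups. Taken as pairs, their deviations from the group means had r from -0.14 to 0.14, over 0.1 in 1 of 6 pairs, and 1 of 12 libraries was closest to its own number. With these pairs as a replicate block there were 0 genes (3.20% at an unadjusted p under 0.05), 7 lists, the 6 above included, and 0 transcripts (Gnao1 transcript 2.17, adjusted p 0.99998). The pairs of consecutive animal numbers had a correlation of -0.05 and gave 0 genes. The median half-width of 0.30 of the interval on the log2 scale limits what smaller changes could be seen.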

Other observations

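All tests in this part were chosen after the results were seen. The interferon response score stood apart in a pair of morphine-sired libraries, at 0.71 in morphine-sired 5 and 0.31 in morphine-sired 6 against -0.28 to 0.04 in the other 10. The animals of this pair have consecutive numbers, 383 and 384, and the labels do not say whether they share a litter or sire. Irf7, a transcription factor of the interferon response, was at 19.9 and 10.5 in these libraries and at 3.63 to 8.91 elsewhere, and Isg15 at 12.1 and 10.2 against 3.81 to 6.49.

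The first principal component held 18.2% of the variance of the tested genes, and its values did not differ between the groups (exact permutation p 0.788). After the sire's treatment was taken into account, 1789 genes outside the list followed the astrocyte score, 1562 the ependymal score and 799 the oligodendrocyte score, against 0 for the microglia score. The sire's treatment held 7.57% of the total sum of squares, less than the 9.09% of a random term. The ependymal score held 17.8%, but it is computed from these same values, so it cannot be compared with a label on equal terms. Morphine-sired 2 stood at -2.03 in this score, against -0.51 to 1.13 elsewhere. The counts of genes that follow a score are likewise drawn from the same values.

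Estimates of some transcripts were all or none. In 827 transcripts the value was 0 in at least 3 libraries and at least 10 TPM in at least 3 others, and for 579 of these the sum of the locus stayed within 2-fold over the 12 libraries. The annotated Rpl34 transcript was at 7.90 to 16.7 in 8 libraries and at 324 to 365 in saline-sired 3 and morphine-sired 2, 3 and 6. Such values add spread to single transcripts and, where symbols differ within a locus, to genes.

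As a hypothesis, the level of Oprm1 may follow the position of the tissue piece. The markers of that score were weakly correlated among themselves (0.136), so it is an uncertain measure of position. Oprm1 rose with the score of thalamic and collicular neurons over the 12 libraries (Pearson's r 0.830, permutation p 0.000960; Spearman's rho 0.804, permutation p 0.00259; adjusted p 0.00307), with r 0.676 without the 2 libraries farthest from the median. Within the groups, r was 0.852 in saline-sired (exact permutation p 0.0306) and 0.873 in morphine-sired rats (exact permutation p 0.0417). It fell with the catecholamine score (r -0.856, permutation p 0.000450; rho -0.888, permutation p 0.000200; adjusted p 0.00267; r -0.729 without 2 libraries). Of the 16 relations computed between Oprm1, Rgs4, Penk and Oprk1 and 4 regional scores, 12 passed an adjusted p of 0.05. Without the 2 libraries farthest from the median, r of Oprk1 weakened with the serotonergic score (-0.635 to -0.380) and the catecholamine score (-0.657 to -0.469). In the other passing relations it stayed at 0.612 or more in size. All relations use the same 12 libraries, so they are not separate pieces of support. The sire's treatment did not separate Oprm1, so its spread of 5.94 to 19.8 TPM may come from dissection, which these data cannot tell from differences between animals.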
